A study of Mus musculus with 15 samples.

How the data were processed

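Total RNA was extracted from Cx3cr1-GFP-positive cells with a column kit and checked on a Bioanalyzer, per the labels' protocols. The reads were aligned with GSNAP to GRCm38, per the submitters' processing notes; the version, the annotation, the library kit and strandedness are not given in the sources used here. Each of the 15 samples has its own table of 36528 NCBI Gene IDs with a pair of values. Per the file headers, the first is the count of reads that align uniquely to the gene model, in raw whole numbers, and the second is nRPKM, the RPKM (reads scaled to gene length and library size) adjusted by a size factor per sample. How the authors computed the size factor of the deposited RPKM is not stated; within each sample the ratio of RPKM to count scaled by the same factor for every gene, and the authors' factors were 0.981 to 1 times those of the effective library sizes computed here. The counts were used for all tests and the RPKM for an added alternative.

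Gene symbols and coordinates came from a RefSeq table of the GRCm38.p6 assembly. It matched 31049 of the IDs, which held between 97.2% and 98.2% of each sample's reads, and 1033 of the genes tested were unmatched. Of 563 symbols in the gene lists 4 were not matched (Gpr56, an older name of Adgrg1 that is in the same list, Trac, Ighm and Iglc2). Samples of a group were compared pair by pair: over 51 pairs the chi-square per degree of freedom of their counts lay between 9.98 and 67.5, so no pair agreed within sampling noise and each sample counted once. Replicate numbers are not shared between the groups, so the samples were not paired.

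Genotype was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on genotype left 13994 genes, TMM scaled the libraries, and a quasi-likelihood model with age and genotype was fitted to all 15 samples. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the size of the log2 fold change divided by the square root of the F statistic, and levels are CPM, counts scaled to TMM-adjusted library sizes. The age coefficient and a genotype by age interaction were tested in the same way. For genes with 1 to 3 wild type reads the ratio of summed reads is given with a 95% counting interval, and the floor for a count of 0 is 3 reads. The reads were summed over the samples of each group, so these intervals cover counting error only and leave out the spread between samples. The reads also carry no stated molecular identifiers.

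The 32 gene lists, of which 13 hold markers of other cell types, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. The preset called 12 lists (9 up, 3 down) and the estimated correlation 4, namely the plaque-associated, interferon, growth factor and lipid lists. Fry called 10 lists as moving in a direction and 17 as changing in either. A sample's score is the mean log2 CPM of the tested members of a list, and scores of cell type markers were compared by an exact two-sided permutation test over all 5005 splits of 9 against 6. The same test was run on the program scores and adjusted over the programs, though the fixed designs named it for cell type markers alone. Each correlation was tested with 100000 resamples. The step was tested on simulated counts with 200 changed genes among 13994: for genotype 38% of genes changed 2-fold and 73% of those changed 4-fold were recovered, with 4.31% false calls, and for age 37% and 68%.

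Designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes App, Psen2 and Cx3cr1, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those called with an average log2 CPM of at least 2, up to 4 members of each list with the smallest adjusted p, and up to 5 genes for age and the interaction; some genes it takes are not reported here. Some lists share members, so their calls are not independent of each other. The plaque-associated list also holds Apoe, Lpl and Ch25h of the lipid list, and Igf1 and Gpnmb of the growth factor list. It holds Ccl6 of the chemokine, Ctsl of the lysosome, Itgax of the complement, and Clec7a and Axl of the phagocytic receptor list too. Cxcl10 is in the interferon and chemokine lists, and Apoe is also a risk gene. The alternatives were no age term, RLE or no scaling, other count filters, DESeq2 1.42.0, limma-voom with quality weights, a robust fit, 1 surrogate variable from sva 3.50.0, the ratio of Xist to Y-linked reads as a covariate, each age alone, and each sample left out in turn. Added after seeing the data were fits without the 4 libraries high in immediate early genes, without the 3 low in Xist, with the immediate early or the neuron score as a covariate, and limma-trend on log2(RPKM + 1).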

Results

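RNA was sequenced from microglia of the mouse cortex, sorted by flow cytometry for green fluorescent protein expressed from the Cx3cr1 locus, a gene that microglia use at high level. The 15 samples came from PS2APP mice (n = 9), a model of Alzheimer's disease that carries human mutant presenilin 2 and amyloid precursor protein transgenes, and from wild type mice (n = 6), at 14 or 15 months of age. At 14 months there were 4 PS2APP and 2 wild type samples, and at 15 months 5 and 4. Total counts per sample ranged from 3664742 to 8455237 with a median of 5867848, and the 10 most abundant genes took between 7.23% and 9.88% of them. The labels do not say that each sample came from a separate mouse, so the p-values measure the spread between these samples. The comparisons asked which genes and gene groups of cortical microglia differ between PS2APP and wild type mice at this age, and whether age within this range or other cells in the sort moved with genotype.

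The transgene and gate genes came first. App, the mouse gene for the amyloid precursor protein, stood at 209 ± 78.1 CPM (counts scaled to the library size; SD, n = 9) in PS2APP and 169 ± 27.3 (n = 6) in wild type, a log2 fold change of 0.30 ± 0.21 (SE; edgeR adjusted p = 0.623). Psen2 stood at 13.2 ± 5.15 and 9.10 ± 5.82 CPM, with a log2 fold change of 0.62 ± 0.38 (adjusted p = 0.563). Cx3cr1, the fractalkine receptor whose locus drives the reporter, stood at 2100 ± 319 and 2571 ± 199 CPM, with a log2 fold change of -0.29 ± 0.12 (adjusted p = 0.340). None of the 3 passed the test, and counts over the mouse gene models were not split between the mouse genes and the human transgenes.

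PS2APP microglia expressed a set of genes that were low or close to absent in wild type microglia. Cst7, which encodes the cysteine protease inhibitor cystatin F, rose from 10.1 ± 6.08 CPM (SD, n = 6) to 473 ± 157 (n = 9), a 47.6-fold increase (log2 5.57 ± 0.39 SE; edgeR adjusted p = 2.6e-08). Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes, rose from 0.793 ± 0.778 to 124 ± 73.0 CPM, and Igf1, insulin-like growth factor 1, from 7.34 ± 5.79 to 152 ± 85.2 CPM. The largest fold changes also included Dkk2, a secreted regulator of Wnt signalling, Hpse, the heparan sulfate-cleaving heparanase, and Mamdc2. In the other direction Gad2, the GABA-synthesising enzyme of inhibitory neurons, fell from a low level.

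Of 13994 genes tested, 165 passed the threshold of 0.05 on the adjusted p, 134 higher and 31 lower in PS2APP (edgeR quasi-likelihood test with age as a covariate). Among them 135 changed by more than 2-fold, 114 upward and 21 downward. In 89 of the 13994 tested genes, 74 of them called, the lowest sample of the higher group lay above the highest of the other, which chance gives in 0.0400% of genes. At an unadjusted p under 0.05 there were 1635 genes, against 699.7 expected by chance. Within the ages the same comparison called 50 genes at 14 months (46 higher) and 65 at 15 months (55 higher). The count was 81 without the 3 libraries low in Xist (PS2APP sample 14, wild type samples 12 and 13), and 34, all of them higher, with the neuron marker score of each sample as a covariate, both chosen after seeing the data. Without the 4 libraries that stood apart in immediate early genes (PS2APP samples 1 and 4, wild type samples 9 and 13) it was 142, of which 95 were among the 165, and without wild type sample 11, which lay far from the rest on the first principal component, it was 185, with 143 of the 165.

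Among the 12 genes with the largest increases, 3 had at most 4 wild type reads in all. Cd28 (7 reads), Trpc4 (9) and Mamdc2 (10) had few as well, so their folds are also uncertain. Dkk2 (chromosome 3, 132085266 to 132180304, GRCm38) had 1 wild type read in all and 16.3 ± 13.2 CPM in PS2APP, a ratio of 596 with a 95% counting interval of 107 to 23589. Baiap2l2 had 2 wild type reads and 14.3 ± 7.55 CPM in PS2APP, a ratio of 257 (interval 71.0 to 2130). Hpse (chromosome 5, 100679484 to 100719716) had 4 wild type reads and reached 39.4 ± 24.3 CPM (log2 8.14 ± 0.62). Mamdc2 rose 172-fold (log2 7.42 ± 0.56), Gpnmb (chromosome 6, 49036518 to 49058182) 138-fold (7.11 ± 0.57), and Cd28, known as a costimulatory receptor of T cells, 43.1-fold (5.43 ± 0.82). Lgi2 rose with a log2 fold change of 4.99 ± 0.67, Cd200r4, a receptor of the CD200 receptor family, with 4.94 ± 0.48, the cation channel Trpc4 with 4.82 ± 0.76, Igf1 with 4.37 ± 0.47 and Ldlrad3 with 4.28 ± 0.50. Each of these genes was higher than the wild type median in 9 of 9 PS2APP samples and kept its call in each of the 15 fits that left out a sample, but with limma-voom Cd28 (adjusted p = 0.0759) and Lgi2 (0.116) were not called. Folds moved by over 1.5 times for Dkk2 without wild type sample 13 (log2 9.58), for Mamdc2 without 9 (8.32), and for Hpse (8.76), Lgi2 (5.68) and Trpc4 (5.64) without 12. Igf1 overlaps an antisense gene, and the sources used here do not say whether counting used strand.

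**Figure D1:**
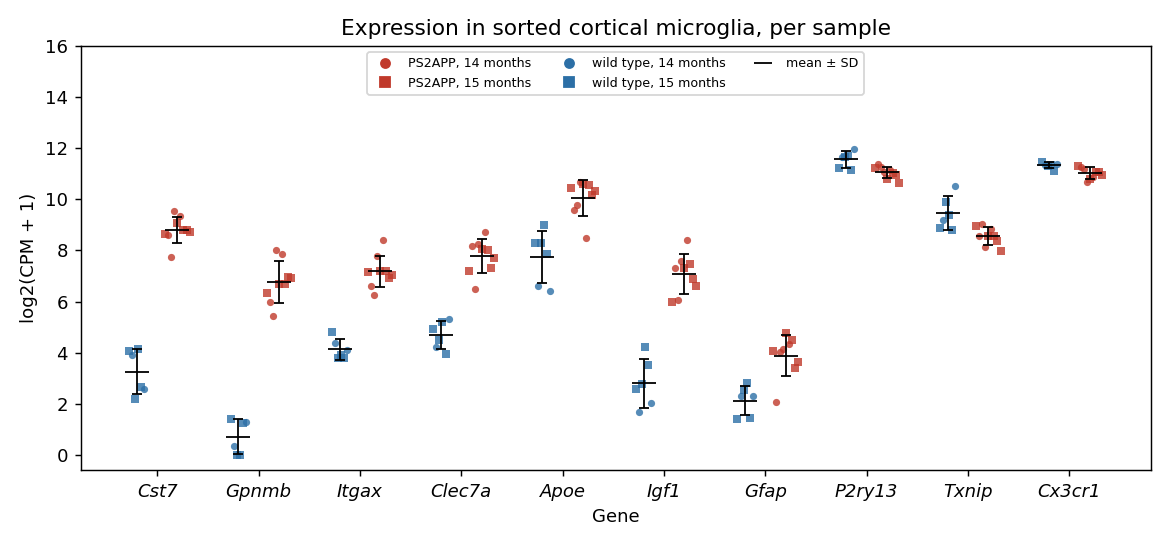
Expression of 10 genes in each sample, as log2(CPM + 1) on the vertical axis, for wild type (blue, n = 6) and PS2APP (red, n = 9) at 14 (circles) and 15 months (squares), with the mean and SD in black. Cst7 averaged 10.1 CPM in wild type and 473 CPM in PS2APP, and Cx3cr1 2571 and 2100 CPM.

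The 12 largest decreases were smaller. Ttr, which encodes the thyroxine carrier transthyretin, went from 69.1 ± 115 CPM (SD, n = 6) to 5.80 ± 7.10 (n = 9), a log2 fold change of -3.40 ± 0.82 (edgeR adjusted p = 0.0405), with a wild type spread larger than its mean. Enpp2, the lysophospholipase D autotaxin, stood at -2.51 ± 0.58. Both rest on few wild type libraries: sample 9 held 299 CPM of Ttr and 101 CPM of Enpp2, and without it they were -2.09 (adjusted p = 0.267) and -1.68 (0.190), or without the 4 libraries apart in immediate early genes -1.47 (0.496) and -0.39 (0.821). Wild type sample 11 held 46.8 CPM of Gad2 and 47.7 of Lsamp, and without it they were at -1.65 (adjusted p = 0.119) and -1.27 (0.146). The others were Gad2 with -2.26 ± 0.53, Baalc with -2.22 ± 0.44, Fam171b with -2.15 ± 0.47, the Wnt receptor Fzd3 with -1.96 ± 0.48, and Slc17a7, the vesicular glutamate transporter of excitatory neurons, with -1.94 ± 0.47. Then came Lsamp (-1.87 ± 0.46), the amyloid precursor-like gene Aplp1 (-1.85 ± 0.39), Ctxn1 (-1.63 ± 0.40), Gm31550 (-1.51 ± 0.37) and Gp9 (-1.48 ± 0.28). Baalc, Aplp1 and Gp9 were called in 15 of 15 fits that left out a sample, Fam171b in 13, Gad2 in 9, Enpp2, Fzd3 and Slc17a7 in 7, Ttr and Ctxn1 in 5, and Lsamp and Gm31550 in 3. With the neuron marker score, which holds Gad2 and Slc17a7, as a covariate none of the 12 was called, and the SEs were mostly larger. Slc17a7 (-0.52 ± 0.44), Fzd3 (-0.95 ± 0.55), Baalc (-1.26 ± 0.48) and Aplp1 (-1.20 ± 0.44) shrank most, and Fam171b, Lsamp, Gp9 and Gad2 shrank by less. Ttr (-4.30 ± 1.14), Enpp2 (-2.55 ± 0.77), Ctxn1 (-1.68 ± 0.52) and Gm31550 (-1.48 ± 0.53) kept about their size or more.

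**Figure D2:**
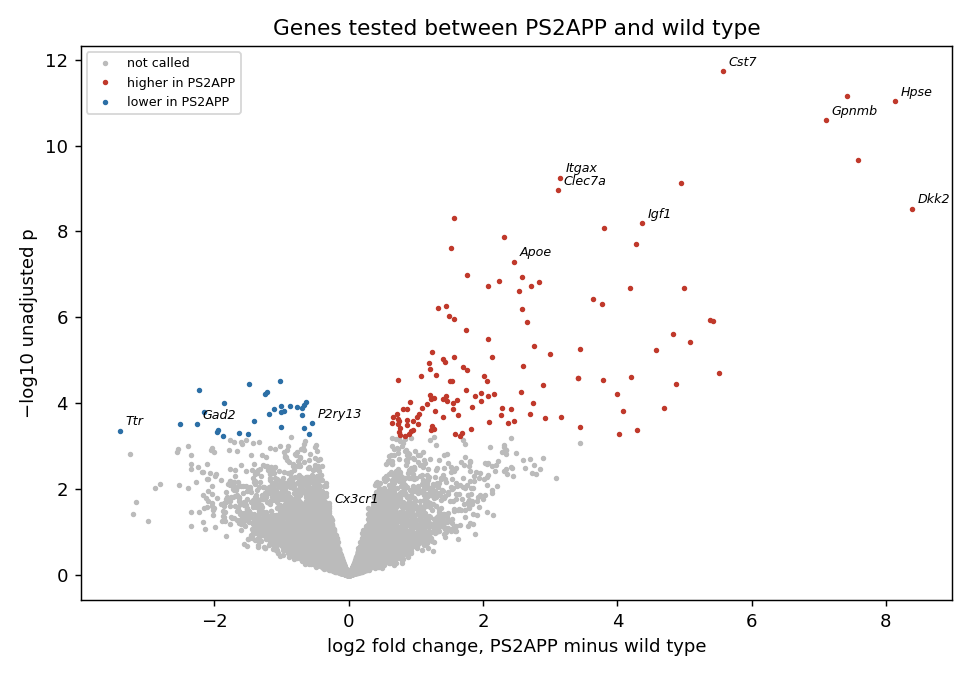
Log2 fold change of PS2APP against wild type (horizontal axis) and −log10 of the unadjusted p (vertical axis) for the 13994 genes tested. Red points are the 134 genes called higher in PS2APP, blue points the 31 called lower, and grey points those not called.

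Genes known from microglia around amyloid plaques rose together. Of 30 tested members of this list, 17 rose, 0 fell and 13 were not called, and 26 rose when adjusted over the list alone. Itgax, the CD11c integrin subunit, rose 8.88-fold from 17.1 ± 5.56 to 157 ± 78.6 CPM, and Clec7a, the beta-glucan receptor Dectin-1, rose 8.69-fold. The list's median log2 fold change was 1.90, 29 of 30 members were positive, and camera gave an adjusted p of 3.9e-40, and an adjusted p = 0.00742 with an estimated correlation. The mean score was higher by 2.41 at 14 months and by 1.99 at 15 months. The list was written from general knowledge of this kind of model, and earlier work on such mice went into that knowledge.

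Homeostatic microglia genes shifted the other way by a small amount. Of 29 tested members, 0 rose and 2 fell, with 8 fallen when adjusted over the list alone. Txnip, a thioredoxin-binding protein, fell 2.02-fold (log2 -1.01 ± 0.22, edgeR adjusted p = 0.0171), and P2ry13, a purinergic receptor, fell 1.46-fold (-0.55 ± 0.13, adjusted p = 0.0304), called in 13 and 8 of the 15 fits that left out a sample. Neither was called without the 4 libraries apart in immediate early genes (-0.67, adjusted p = 0.0768, and -0.50, 0.117) or with the Xist ratio as a covariate (0.0607 and 0.0608). Entpd1 (-0.43 ± 0.12; called without wild type sample 12, adjusted p = 0.0402) and Selplg (-0.46 ± 0.14; called at -0.66, 0.0444, without the 4 libraries) did not pass. The median was -0.30 with 28 of 29 members negative, and the camera adjusted p of 2.1e-08 became an adjusted p = 0.0529 with an estimated correlation.

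Interferon-induced genes rose as a group. Of 30 tested members of the type I interferon list, 7 rose and 0 fell, and 22 rose when adjusted over the list alone. Oasl2, of the oligoadenylate synthetase family, rose 6.28-fold from 10.1 ± 8.48 to 61.1 ± 23.2 CPM (log2 2.65 ± 0.40). Ifit2 rose 4.15-fold and Ifi44 15.9-fold, the latter not called without PS2APP sample 15 (edgeR adjusted p = 0.0541), and Trim30a rose 1.66-fold with the smaller spread of 222 ± 26.4 against 134 ± 18.2 CPM. The median log2 fold change was 1.23, and the adjusted p of camera was 1.8e-21, or an adjusted p = 0.0233 with an estimated correlation. The mean score was higher by 1.60 at 14 months and 1.10 at 15 months.

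Antigen presentation genes of class I and class II differed in their counts of calls. In the MHC class I list 4 of 18 tested members rose and 0 fell, with 7 risen when adjusted over the list alone. H2-D1 rose 2.10-fold, the class I transactivator Nlrc5 3.91-fold, H2-M3 2.74-fold and H2-Q6 3.53-fold, the last called in only 4 of the 15 fits that left out a sample and Nlrc5 in 14, all but that without wild type sample 13. All 4 lost the call without the 4 libraries apart in immediate early genes (edgeR adjusted p 0.0579 to 0.0948) and without the 3 low in Xist (0.0544 to 0.0972). Without the 4 libraries H2-D1 stood at log2 0.98 (1.07 with all samples), Nlrc5 at 1.69 (1.97), H2-M3 at 1.44 (1.46) and H2-Q6 at 2.14 (1.82). Camera called the list at an adjusted p of 1.2e-07, and this was lost at an adjusted p = 0.219 with an estimated correlation. In the MHC class II list none of 13 members was called, 1 when adjusted over the list alone, with Cd74, the invariant chain, at a log2 fold change of 0.89 ± 0.27 and H2-Aa at 0.73 ± 0.36 (camera adjusted p = 0.0946). Cd74 was called without wild type sample 11 (1.08, edgeR adjusted p = 0.0426), with limma-voom (0.0287) and with 1 surrogate variable (0.0384). The mean class I score was higher by 1.32 at 14 months, with 2 wild type samples, and by 0.40 at 15 months. The class II difference was 0.96 at 14 months and -0.12 at 15 months. None of the 4 class I genes was called at 15 months alone (edgeR adjusted p 0.126 to 0.278), and at 14 months only Nlrc5 was (0.00643). No gene passed the test of a genotype effect that differs between the ages. That test had little power, with 1% of genes changed 2-fold and 25% of those changed 4-fold recovered in simulated data. Its log2 estimates were -2.26 for Nlrc5 (edgeR unadjusted p = 0.00177), -0.98 for H2-D1 (0.00907), -1.30 for H2-M3 (0.0215) and -0.13 for H2-Q6 (0.886). For Cd74 and H2-Aa they were -1.39 (0.00611) and -1.59 (0.0234). A difference between the ages is thus neither shown nor excluded. Whether the lists differ from each other was not tested. H2 genes have near-identical copies, so counts of uniquely aligned reads for single members are uncertain.

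Some growth factor, matrix and lipid genes rose, several of them also members of the plaque-associated list (Igf1, Gpnmb, Apoe, Lpl and Ch25h). In the growth factor and matrix list 7 of 21 tested members rose and 0 fell, with 10 risen when adjusted over the list alone, among them Lox, the collagen cross-linking lysyl oxidase (13.6-fold, log2 3.77 ± 0.53), and Mmp12, macrophage elastase (4.22-fold). The list's camera adjusted p was 2.1e-08, and an adjusted p = 0.00948 was found with an estimated correlation. In the lipid list 4 of 24 rose and 0 fell, with 7 risen when adjusted over the list alone. Apoe, the apolipoprotein E gene, rose 5.50-fold from 258 ± 161 to 1165 ± 425 CPM, Lpl, lipoprotein lipase, 5.98-fold, Ch25h, cholesterol 25-hydroxylase, 10.8-fold (log2 4.33 without wild type sample 2, against 3.44), and Nceh1, a cholesteryl ester hydrolase, 2.84-fold. Camera gave the lipid list an adjusted p of 4.8e-06, or an adjusted p = 0.00948 with an estimated correlation. Of 22 cholesterol biosynthesis genes none was called (camera adjusted p = 0.0967).

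Chemokine, lysosome, glycolysis and complement genes passed camera with fewer called members. Of these Ccl6, Ctsl and Itgax are also in the plaque-associated list, and Cxcl10 is also in the interferon list. In the chemokine list 2 of 20 rose and 3 did when adjusted over the list alone, and the 2 were Cxcl10 (3.10-fold, called in 11 of 15 fits without a sample) and Ccl6 (2.35-fold, called in only 4 of 15), with a camera adjusted p = 0.00704 and an adjusted p = 0.212 with an estimated correlation. In the lysosome list 1 of 32 rose, the protease Ctsl (1.80-fold, log2 0.85 ± 0.21, called in 6 of 15 such fits), and 10 did when adjusted over the list alone. Its camera adjusted p = 0.00621 became an adjusted p = 0.487 with an estimated correlation, and Atp6v0d2 (3.45 ± 0.89) and Ctsb (0.67 ± 0.21) were not called. Atp6v0d2 was called at 6.04 (adjusted p of 3.8e-04) without wild type sample 9 and at 5.64 without the 4 libraries apart in immediate early genes, and Ctsb at 0.88 (0.0190) without wild type sample 11. In the glycolysis list 1 of 19 rose, Hif1a, the hypoxia-inducible transcription factor (2.30-fold), 2 did when adjusted over the list alone, and Pfkl stood at 0.70 ± 0.22 (camera adjusted p = 0.00141, and adjusted p = 0.234 with an estimated correlation). In the complement list 3 of 17 rose, C3 (5.93-fold), C2 (17.0-fold) and the integrin Itgax, and 3 did when adjusted over the list alone. C3 was not called with limma-voom (adjusted p = 0.0592). C2 had at most 0.831 CPM in any wild type sample and 0.249 to 8.78 CPM in PS2APP, so its fold rests on few reads and is uncertain. It was called in 7 fits without a sample, at 4.80 without wild type sample 5 against 4.09 with all, and not without wild type sample 12 (edgeR adjusted p = 0.0513) or 13 (0.0550), without the 4 libraries (0.113) or with the Xist ratio (0.110). The count filter dropped it in the other fits that left out a sample. The complement list's camera adjusted p = 0.0493 became an adjusted p = 0.434 with an estimated correlation, and its median was 0.02 with 8 of 17 members negative. The chemokine call was lost without wild type sample 5 (adjusted p = 0.0692, camera) and the lysosome call without PS2APP sample 8 (0.0577) or wild type sample 13 (0.111). The complement call was lost without any of PS2APP samples 1, 3, 4, 6, 7, 8, 10 and 15 or wild type samples 9, 12 and 13 (0.0569 to 0.233).

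Camera called none of the MHC class II, phagocytic receptor, cholesterol, proliferation, NF-kB, oxidative phosphorylation and Alzheimer risk gene lists with all samples. The exact permutation test of scores did pass phagocytic receptors (adjusted p = 0.00206), cholesterol (0.0154) and proliferation genes (0.0445). It did not pass MHC class II (0.194), NF-kB (0.883), oxidative phosphorylation (0.608) or risk genes (0.606). Of the programs called by camera it passed all but the immediate early genes. Without wild type sample 11 camera called the MHC class II (adjusted p = 0.00277), phagocytic receptor (0.00335) and cholesterol (0.0318) lists. It also called MHC class II without PS2APP sample 14 (0.0419) or 15 (0.0478), the phagocytic list without PS2APP sample 7 (0.0364), 14 (0.0444) or 15 (0.0311), and the NF-kB list, lower, without wild type sample 12 (0.0427). Of 24 phagocytic and pattern recognition receptors 2 rose, Clec7a and the receptor kinase Axl (5.81-fold), and 3 did when adjusted over the list alone, while the median was -0.05, the mean 0.40 and camera gave the direction up (adjusted p = 0.0661). None of 23 proliferation genes was called, with Tyms at 0.88 ± 0.28 and Top2a at 1.03 ± 0.38 (camera adjusted p = 0.0967), but Top2a was called without wild type sample 11 (1.47, edgeR adjusted p = 0.0253) and with 1 surrogate variable (0.0285). None of 20 genes of the NF-kB inflammatory list was called, with Il1a at -1.11 ± 0.39 and Nlrp3 at -0.58 ± 0.21 (camera adjusted p = 0.186). Wild type samples 9 and 13, both high in immediate early genes, held 539 and 931 CPM of Il1a, against 142 to 186 in the other wild type samples. Their NF-kB scores were 5.34 and 5.69 (other wild type 3.89 to 4.44), and 9 of 9 PS2APP scores lay above the wild type median. None of 30 oxidative phosphorylation genes was called (camera adjusted p = 0.245). Of 27 mouse orthologues of Alzheimer risk genes 1 rose, Apoe, also the count when adjusted over the list alone, with a median of -0.01, a mean of 0.04 and a camera adjusted p = 0.791.

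**Figure D3:**
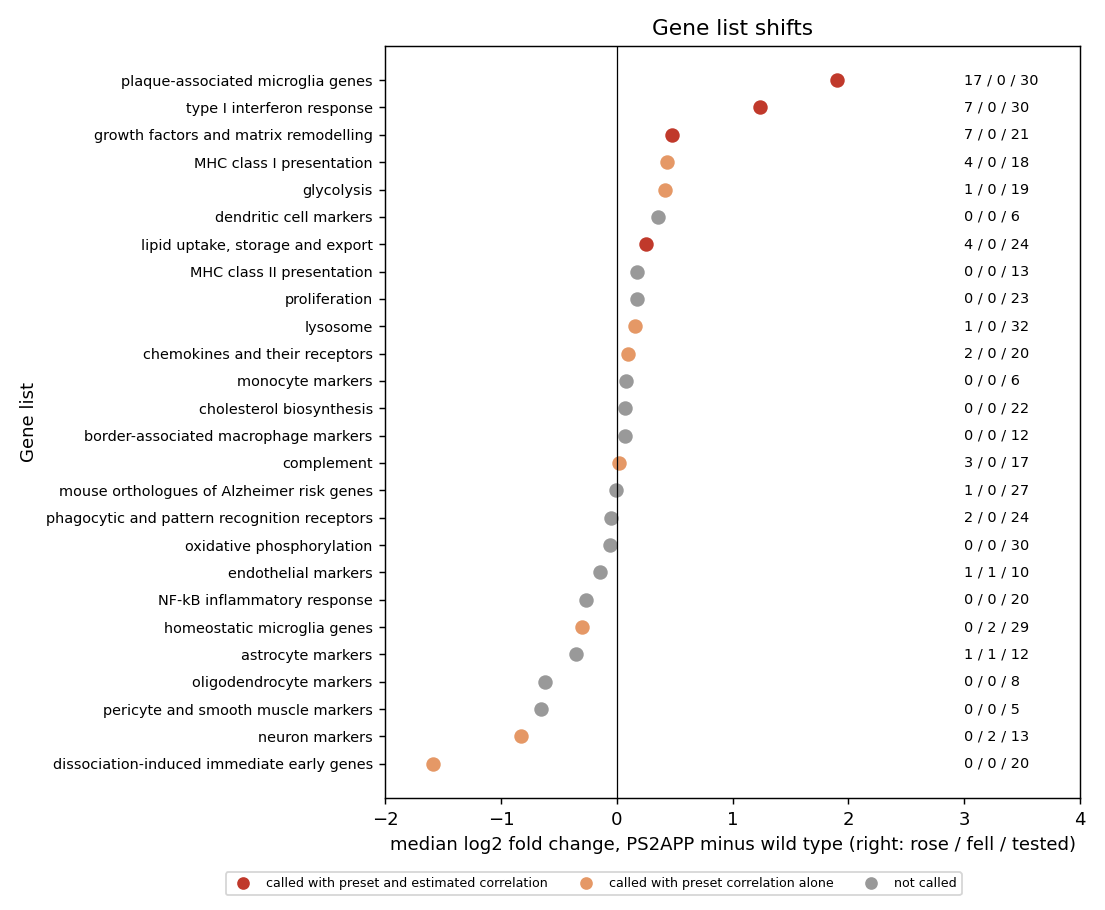
Median log2 fold change of PS2APP against wild type (horizontal axis) for each list with at least 5 tested members (vertical axis), with the numbers of members that rose, fell and were tested at the right. Red lists passed camera with the preset and the estimated correlation, orange lists with the preset correlation alone, and grey lists did not pass; 12 of 32 lists passed with the preset correlation and 4 with the estimated.

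Immediate early genes, which cell dissociation is known to induce, separated 4 libraries from the other 11. Their mean log2 CPM was 6.75 and 6.82 in PS2APP samples 1 and 4 and 7.85 and 8.73 in wild type samples 9 and 13, against 3.41 to 4.06 in the others. No member of 20 was called, with Klf2 at -2.89 ± 1.01 and Btg2 at -1.55 ± 0.62, and 0 were when adjusted over the list alone. Without PS2APP sample 1 Klf2 was called at -4.00 (edgeR adjusted p = 0.0472). Camera called the list lower in PS2APP (median -1.59, adjusted p = 0.0232), with an adjusted p = 0.630 with an estimated correlation, and the exact permutation test of the scores gave p = 0.527 (two-sided, 9 against 6 samples). Without those 4 libraries the direction of the camera statistic turned, with the median close to 0 (-0.02, adjusted p = 0.179), and the lysosome (0.213), complement (0.353) and glycolysis (0.179) adjusted p of camera rose above the threshold. The immediate early call was also lost without PS2APP sample 3, 6, 8 or 10 (0.0578 to 0.0681) or wild type sample 9 (0.487) or 13 (0.892).

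Marker genes of other cell types showed lower neuronal expression in PS2APP. Of 13 neuron markers 0 rose and 2 fell, Gad2 and Slc17a7, with 6 fallen when adjusted over the list alone, and Nefl (-2.34 ± 0.69) and Syt1 (-1.28 ± 0.38) were not called. Syt1 was called without PS2APP sample 8 (-1.17, edgeR adjusted p = 0.0450) and at 15 months alone (-1.62, 0.0283), and Nefl with limma-voom (-2.42, 0.0390). The neuron score was 2.88 ± 0.76 (SD, n = 9) in PS2APP and 3.92 ± 0.45 (n = 6) in wild type, lower than the wild type median in 9 of 9 samples (exact permutation test, two-sided, p = 0.00619, adjusted over 13 lists 0.0403). Camera gave an adjusted p of 2.6e-06, and an adjusted p = 0.130 with an estimated correlation. The score of oligodendrocyte precursor markers was higher by 1.56 (exact permutation p = 4.0e-04, adjusted 0.00519), from 2 tested members, and camera called this list only without PS2APP sample 3 (adjusted p = 0.0341) among the fits that left out a sample. Of these Cspg4, the NG2 proteoglycan, rose 18.2-fold from 0.831 ± 0.601 to 14.9 ± 7.99 CPM, though limma-voom did not call it (adjusted p = 0.0937), and Ptprz1 stood at -0.47 ± 0.39.

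Astrocyte and endothelial markers went both ways. Of 12 astrocyte markers 1 rose, the intermediate filament gene Gfap (4.23-fold, from 3.66 ± 1.72 to 15.4 ± 6.79 CPM), and 1 fell, the glutamate transporter Slc1a2 (2.01-fold). Gfap, at log2 2.08 with all samples, was not called with limma-voom (2.39, adjusted p = 0.0816). It was also not called without the 3 libraries low in Xist (2.05, edgeR adjusted p = 0.0775) or without the 4 apart in immediate early genes (2.25, 0.0623). Slc1a2 was highest in wild type samples 9 and 13 and was not called without 9 (edgeR adjusted p = 0.0629), 13 (0.0838) or the 4 libraries apart in immediate early genes (-0.70, 0.176). Slc4a4 (-1.67 ± 0.45; called without wild type sample 11 at -1.85, 0.0146) and Atp1b2 (-0.79 ± 0.30) were not called, and adjusted over the list alone 1 rose and 3 fell. Of 10 endothelial markers 1 rose, the VEGF receptor Flt1 (4.82-fold), and 1 fell, the adhesion molecule Pecam1 (2.31-fold), as when adjusted over the list alone; their median was -0.15 and mean 0.08. Flt1 was called in 10 of 15 fits without a sample, and not without wild type sample 5, 9 or 13, PS2APP sample 10 or 15 (edgeR adjusted p 0.0501 to 0.0675) or the 4 libraries (0.110), with limma-voom (0.0702) or with the Xist ratio (0.0624). The exact permutation adjusted p of the scores was 0.655 for astrocytes and 0.844 for endothelium. None was called among 8 oligodendrocyte markers (score adjusted p = 0.121, exact), 5 pericyte markers (0.527), 12 border-associated macrophage markers with Mrc1 at 0.36 ± 0.29 (0.791), and 6 monocyte markers with Ccr2 at 0.14 ± 0.20 (0.844). The same held for 6 dendritic cell markers with Clec9a at 2.32 ± 0.72 (exact adjusted p = 0.0589), 2 B cell markers with Cd22 at 1.04 ± 0.29 (0.527), and 1 tested marker each of neutrophils (Csf3r, 0.31 ± 0.18), of T and NK cells (Klrd1, -0.91 ± 0.61) and of erythrocytes. Leaving out 1 sample also gave calls: Clec9a (3.64, edgeR adjusted p = 0.0111) and the dendritic list (camera, 0.0157) without wild type sample 12, Cd22 (1.29, 0.0175) without 9, and, lower, the astrocyte list without 2 (0.0347) or 5 (0.0354) and the erythrocyte list without 5 (0.00407) or 12 (0.00778). The low-count filter was run anew in these fits (14238 genes tested without wild type sample 5, 13994 with all), so the tested members of a list can differ. The erythrocyte list had 1 tested member at -0.23 with all samples, but a median of -4.24 without 5 and -4.25 without 12. Its calls are thus not those of the same tested list.

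**Figure D4:**
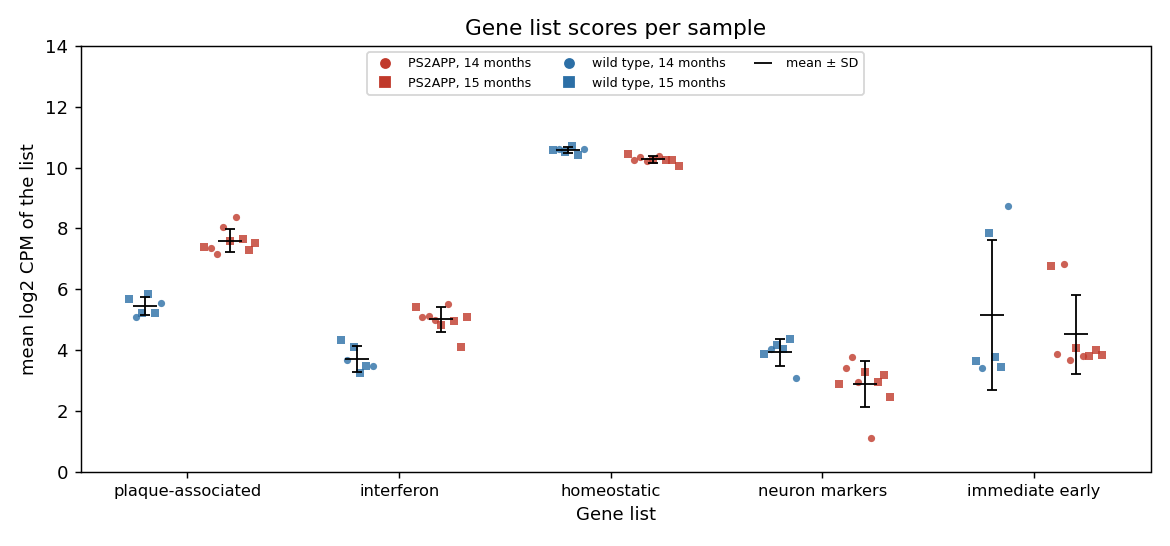
Mean log2 CPM of 5 gene lists (vertical axis) in each wild type (blue, n = 6) and PS2APP sample (red, n = 9) at 14 (circles) and 15 months (squares), with the mean and SD in black. The neuron score averaged 2.88 in PS2APP and 3.92 in wild type, and the immediate early score was above 6.7 in 4 samples.

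Age within this range was then compared, with genotype as a covariate. None of the 13994 genes passed between 15 (n = 9) and 14 months (n = 6) in edgeR's test, the smallest adjusted p being 0.431. At an unadjusted p under 0.05 there were 1112 genes, more than the 699.7 expected by chance. DESeq2 called 10 and limma-voom with quality weights 0. No gene passed the test of a genotype effect that differs between the ages either (edgeR, smallest adjusted p 0.548, 1038 genes at an unadjusted p under 0.05, against 699.7 expected by chance), where DESeq2 called 6 and limma-voom 0. In data simulated with these depths the interaction test recovered 1% of genes changed 2-fold and 25% of those changed 4-fold, so smaller differences were not detectable with 2 wild type samples at 14 months.

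Finally, the plaque-associated and homeostatic scores were compared across the 9 PS2APP samples. Pearson's r was 0.02 (permutation p = 0.961) and Spearman's rho -0.20 (permutation p = 0.612), so no relation was detected, this being the only relation computed. Without PS2APP samples 8 and 6, the farthest from the median plaque-associated score, r was -0.40. The ages hold 4 and 5 of these samples, too few for a value within each.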

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

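The tests of other cell types, of wild type sample 11, of carry-over and of the age splits were chosen after the result was seen; the second neuronal list and the genotype splits were set before their results. Of 100 splits of the samples into groups of 9 and 6, only the real split called as many as the 165 genes between genotypes. The highest of the others called 41. Chance is thus unlikely but not excluded, since only 100 splits were drawn. The other splits also mixed PS2APP and wild type samples within a group, which can widen the spread and lower their calls. Differences between the libraries that go with genotype, such as that of the neuron score, are not addressed by these splits. For the 0 genes between 15 and 14 months all 100 splits called as many, as any split must, so this test says nothing about age; 4 of the other splits called any gene, at most 68.

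Samples far from the others of their group were sought by Dixon's ratio, the gap to the nearest sample over the range. It was taken on scores and on log2 CPM, and flagged above 0.625 (n = 6) or 0.493 (n = 9). Among 248 groups examined, 19 stood out where chance would give 12.4 if values were normally distributed, and 15 of the 19 were on the low side. The log scale stretches low values, a read against zeros gives a ratio of 1 (Dkk2, Olfr115), and Klrd1 counts as both gene and list. The type I interferon score of PS2APP sample 14 was 4.09, against 4.82 to 5.50 in the other PS2APP samples. The neuron score of PS2APP sample 8 was 1.10 (others 2.45 to 3.75). The T and NK cell score of PS2APP sample 1, which is Klrd1 alone, was -1.50 with Klrd1 at 0 CPM (others 1.59 to 9.46). In PS2APP samples the low values were Cd28 in sample 1 at 0.213 CPM (others 3.45 to 21.9), H2-Q6 in sample 14 at 3.98 (17.0 to 27.9), Apoe in sample 8 at 355 (769 to 1642), Syt1 in sample 8 at 0.747 (8.72 to 15.1), Gfap in sample 3 at 3.23 (9.46 to 26.1) and Pecam1 in sample 15 at 6.14 (12.5 to 21.7). The high value was H2-Aa in sample 8 at 679 CPM (127 to 288). In wild type the low values were Entpd1 in sample 12 at 1046 CPM (1414 to 1617), H2-M3 in sample 5 at 7.20 (25.2 to 51.4), Cxcl10 in sample 11 at 0.622 (5.52 to 14.3), Ccr2 in sample 2 at 15.0 (27.1 to 33.3) and Myo5a in sample 11 at 31.5 (68.0 to 88.8). The high values were Ctsb in sample 11 at 4885 CPM (2256 to 2909), Dkk2 in sample 13 at 0.132 (others 0) and Olfr115 in sample 2 at 0.981 (others 0).

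Cspg4, Gfap and Flt1, markers of other cell types, were higher in PS2APP. More of those cells in the sort would raise their other markers too, yet with the filter on low counts removed, the other markers at no more than 20 CPM in wild type had a median log2 fold change of -1.01 over 6 oligodendrocyte precursor genes (11.5 CPM together in PS2APP, 17.2 in wild type) and -0.72 over 9 pericyte genes (22.4 and 30.7 CPM). The medians were -0.43 over 9 astrocyte genes (35.4 and 55.5 CPM) and -0.29 over 9 endothelial genes (30.6 and 37.8 CPM). Each median plus 2 standard errors lay below the gene's own fold change minus 2 standard errors, which argues against more of those cells as the source of the 3 increases. Higher expression of these genes by the few such cells present was not tested and stays open, as does expression by the sorted cells themselves.

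Cd28, Cd5, Il18rap and Klrb1b, genes known from lymphocytes, were higher in PS2APP, the last 3 chosen after their values were seen (log2 2.70 ± 0.60, 2.75 ± 0.58 and 3.44 ± 0.81). Cd5 was called in 12 of 15 fits that left out a sample, not without wild type sample 2, 5 or 13 (edgeR adjusted p 0.0542 to 0.0673). Klrb1b was called in 6 of 15, moving to 4.53 without wild type sample 12 and 2.75 without PS2APP sample 1, and not without the 4 libraries apart in immediate early genes (2.29, edgeR adjusted p = 0.276), and PS2APP samples 1 and 8 held 18.3 and 16.4 CPM of it against 1.49 to 6.13 in the others. T cells in the sort would bring the Cd3 genes. Cd3d, Cd3e and Cd3g together changed by -1.56 CPM, with 1 read in PS2APP and 70 in wild type, while Cd28 gained 9.66 CPM (473 reads against 7). This argues against T cells as the source; NK cells, which carry less Cd3, are not excluded by it, and Klrd1, which they express, was not called.

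Neuron markers were lower in PS2APP, and with the neuron score as a covariate the genes called fell to 34, a fit that also removes genotype difference since the score itself differs. Wild type sample 11, which lay apart on the first principal component, had a neuron score of 4.03, near the wild type mean of 3.92. Leaving it out could thus change little, and the score difference without it was -1.02 (exact permutation p = 0.0155). The lowest score, 1.10, was in PS2APP sample 8, and the difference without that sample was not computed. A lower carry-over of every brain cell type may account for it and is not excluded: of 39 low-level markers of the other brain cell types, without Cspg4, Gfap and Flt1, 33 were negative, with a negative median in each list, and the neuron median differed from theirs by -0.41 ± 0.53 (SE, genes taken as independent). Against it, the neuron score fell by more than the astrocyte score, by 0.90 (exact p = 0.0458), but that rests on Gfap, without which it was 0.71 (exact p = 0.111), and against oligodendrocytes it was 0.61 (exact p = 0.111). A second list of 20 neuronal genes not looked at before also had a lower score, by a difference of -0.63 (exact p = 0.0298). Of the 20, 3 were positive and none was called, and without wild type sample 11 the exact p was 0.0564. A lower carry-over of every brain cell type would lower this list too. It thus cannot tell less neuronal RNA alone from that, and both stay open. Whether the neuronal RNA came from carry-over in the sort or from neuronal material taken up by microglia was not tested.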

How the results depend on the processing

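The count of 165 genes between genotypes stayed within 1.5 times in the fits without an age term, with RLE or no scaling, with limma-voom, a robust fit, a surrogate variable or the Xist ratio, and between 118 and 188 when any sample was left out, keeping 113 to 156 of the 165; limma-voom kept 133, the surrogate variable 149 and the Xist ratio 116 of them. The count was 648 without a low-count filter (54.0% higher, against 81.2%), 388 with DESeq2 (67.3% higher), 50 at 14 and 65 at 15 months alone (fewer samples), and, among settings chosen after seeing the data, 81 without the 3 libraries low in Xist and 34 with the neuron score; the other causes were not tested. For the interaction DESeq2 called 6 genes and leaving out a sample 0 to 3, where a lone wild type sample at 14 months is assumed to vary like the other groups; for age DESeq2 called 10, and leaving out a sample 0. Lists called fell from 12 to 4 with an estimated correlation and ranged from 9 to 15 without a sample. The 2 marker scores called stayed 2 with median scores and with RLE, the settings run for them. For the oligodendrocyte precursor list, with 2 tested members, the median is the mean, so median scores could not change its result. The correlation reversed to -0.20 with median scores and ranged from -0.39 to 0.17 without a sample. Over 92 named genes 2477 of 2923 values stayed on their side of the threshold, 395 lost and 49 gained a call, and 2 reversed, neither called: Ccr2 to -0.089 at 14 months and Ptprz1 to 0.098 without the libraries low in Xist. With limma-voom the named genes losing a call were Cd28, Lgi2, Ttr, Enpp2, Gad2, Gm31550, Gp9, Ifi44, H2-Q6, C3, C2, Gfap, Cspg4, Flt1, Il18rap, Klrb1b and Slc45a2, and Cd74, Ctsb, Nefl and Cd22 gained one. DESeq2 gained Atp6v0d2, Cd22, Cd74, Clec9a, Entpd1, Nefl, Pfkl, Slc4a4, Syt1 and Tyms. Without the 3 libraries low in Xist the losses included Ch25h, Nceh1, Pecam1 and Cd5. Over lists 607 of 672 values stayed, 35 lost and 16 gained a call, and 14 reversed the direction of the test. The low-count filter was run anew in each fit that left out samples, so the tested members of a list can differ between fits. Whether that caused the reversals was not tested. As list medians these were Alzheimer risk genes at -0.0081 (fry), and NF-kB at 0.089 and immediate early genes at -0.015 without the 4 libraries. The rest turned when a wild type sample was left out; over all left-out samples medians ranged from -0.085 to 0.015 for risk genes (turned without 11), -0.33 to -0.021 for NF-kB (13), -2.09 to -0.43 for immediate early genes (13), -0.38 to 0.43 for border-associated macrophages (13) and -0.066 to 0.18 for monocytes (2 and 5). They ranged from -1.66 to 0.36 for neutrophils (2, 5 and 12), 0.086 to 0.36 for transgene and gate genes (5) and -0.33 to 0.052 for endothelium (12). At totals from 3664742 counts, genes under a few CPM rest on few reads.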

Other observations

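Trpm1, Trpm6, Psat1, Acaca, Olfr112 and Olfr115, called genes outside the fixed lists and chosen after their values were seen, were higher in PS2APP microglia. The melastatin channels Trpm1 (3 wild type reads, ratio 51.9 with a 95% counting interval of 17.5 to 254; log2 5.37, and 6.13 without wild type sample 13) and Trpm6 (log2 5.08 ± 0.83, edgeR adjusted p = 0.00133, from 5 wild type reads, and 5.89 without wild type sample 13) joined Trpc4. Psat1, an enzyme of serine synthesis, rose 2.74-fold from 34.7 ± 10.7 CPM (SD, n = 6) to 95.3 ± 22.6 (n = 9), and Acaca, which makes malonyl-CoA for fatty acid synthesis, 2.98-fold from 11.5 ± 1.65 to 34.4 ± 10.1 CPM. The olfactory receptor genes Olfr112 (log2 2.58 ± 0.37, 7.44 ± 5.74 to 41.6 ± 12.9 CPM) and Olfr115 (4.69 ± 1.01, 6 wild type reads, all in sample 2) rose, Olfr115 being called in 8 fits that left out a sample, at 7.57 without wild type sample 2, and not without 13 (edgeR adjusted p = 0.0503) or the 4 libraries apart in immediate early genes (0.0954), with near-identical family copies leaving single members uncertain.

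Xist had between 19046 and 42411 reads in 12 samples and 134, 356 and 67 reads in wild type samples 12 and 13 and PS2APP sample 14, whose Y-linked genes had 1793, 3415 and 1366 reads against at most 10 in the others. The labels give no sex, but Xist is expressed in female cells and Y-linked genes in male cells. By these reads wild type samples 12 and 13 and PS2APP sample 14 are male and the other 12 female. The fits without the libraries low in Xist and with the Xist ratio are thus fits that take account of sex.

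Gpnmb, Trpm1, Slc45a2 and Myo5a, genes known from pigment cells driven by the factor MITF, were higher in PS2APP, Slc45a2 by 4.02 ± 0.99 and Myo5a by 1.33 ± 0.19 (log2, SE). Slc45a2 was called in only 4 fits that left out a sample, at 4.80 without wild type sample 13, its call was lost without 2, 5, 9, 11 or 12, and the count filter dropped it in the rest. A hypothesis of a wider rise of MITF and TFE targets was set down before the other members were looked at. Of 23 members 11 were tested, among them the factors Mitf, Tfeb (-0.46) and Tfe3 (-0.28) themselves. The score of the 11 was higher by 0.20 ± 0.06 (SE; exact permutation test, p = 0.00539, 9 against 6 samples), a small rise, and by 0.16 (p = 0.0180) without wild type sample 11. Lysosome (0.32) and glycolysis (0.34) scores rose more, and that of oxidative phosphorylation (-0.08) did not rise. The test thus does not show a rise particular to these genes. No member was called, 5 of 11 were negative, and Mitf itself stood at 0.65 ± 0.19 (edgeR adjusted p = 0.113). The rise may thus be carried by few members.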
